A study of Homo sapiens with 12 samples.

How the data were processed

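Gene expression was measured in the glucocorticoid-sensitive T-cell acute lymphoblastic leukemia line CCRF-CEM-C7H2 on Affymetrix HG-U133 Plus 2.0 arrays. The cells had received 100 nM dexamethasone, a synthetic glucocorticoid, or 0.1% ethanol, its carrier, and RNA was taken at 6 h and at 24 h. Each of the 4 groups held 3 arrays, 1 per independent experiment, so 12 arrays were used and no RNA was pooled. The experiments carried the numbers 0, 1 and 3 at 6 h and 1, 2 and 3 at 24 h.

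The deposited values are log2 expression values per probe set, 1 table for all arrays, made by the authors with GCRMA in R 2.6, per the submitters' processing notes. GCRMA corrects the background by probe sequence, normalizes the quantiles across arrays and summarizes the probes of a set, as it does by default. Its settings, and which arrays were normalized together, are not given in the sources used here. The values fit that description: all 12 arrays had near-equal quantiles, with medians from 3.01 to 3.12. The signal over background set the depth: between 22560 and 22999 probe sets per array (41.3 to 42.1%) reached a log2 of 4. Arrays of 1 group correlated with each other at Pearson's r of 0.997 or more across probe sets.

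The table held 54675 probe sets. The 62 control probe sets were left out of the gene tests and read separately. By the platform's annotation 41097 probe sets carried 1 gene symbol, 1801 several and 11777 none, and symbols were brought to the names of the GRCh38.p14 RefSeq gene table through Entrez numbers where these were listed. Probe sets with a log2 of at least 4 on at least 3 of the 12 arrays were tested (23265, of which 19166 had 1 symbol). Where 1 value per gene was needed, the tested probe set with the highest mean over all arrays stood for its gene (9947 genes). Probe sets with several symbols or none were tested and counted, but not named.

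A group-means model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and empirical Bayes moderation. It tested dexamethasone minus ethanol at 6 h and at 24 h, the difference between these responses, and ethanol at 24 h minus ethanol at 6 h. P values were adjusted by Benjamini-Hochberg over the tested probe sets, and an adjusted p under 0.05 counted as a change. Errors given with ± are limma's standard errors of log2 differences (n = 3 arrays per group). All of these p values measure the spread among independent experiments of 1 cell line. The numbers of the experiments pair the samples: arrays of the same number correlated, after their group means were taken off, at r of 0.417, 0.627 and 0.609 at 6 h and 0.286, 0.238 and 0.424 at 24 h, and no other pair of a dexamethasone with an ethanol array exceeded 0.0500. The model set before the data were examined had no term for the experiment, and tests with the experiment as a block are given for lists whose calls, in all or in 1 direction, moved by more than 1.5 times and for some single results.

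Scan codes in the labels put the arrays into 3 batches: dexamethasone at 6 h, ethanol at 6 h, and all 6 arrays of 24 h. At 6 h the batch and the treatment cannot be told apart, and no fit with a batch term can be had there. At 24 h all arrays lay in 1 batch. The comparison of the ethanol arrays between the times also crosses batches. The difference between the responses holds the 6 h comparison, and with it the same batches.

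Before the data were examined, 21 gene lists were written, among them glucocorticoid receptor targets, cell death, growth, lineage and stress genes, and markers of other cell types, and a list of 130 genes known to host microRNAs, as primary microRNA transcripts (pri-miRNAs). Lists were tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. A host was also tested with p values adjusted over the list alone. The microRNAs in a host were read from the spans in the GRCh38.p14 table, which gives no strand. The probe sets that the study took as pri-miRNA probe sets are not given in the sources used here, and that subset was not rebuilt.

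Genes were named by a rule set before the data were examined. Per time, it took the 8 largest rises and the 8 largest falls past the test with the same direction in all 3 same-numbered experiments, 6 check genes (NR3C1, TSC22D3, FKBP5, BCL2L11, MYC and CCND3), the 4 members with the smallest p in each list, and up to 8 hosts in each direction. For the difference between the times it took the 5 largest in each direction. Some of the genes so taken are not given here. Members behind a count of 5 or fewer that this rule did not reach were named too, and are marked as chosen after their values were seen. A gene at background, below a log2 of 4 on all 3 arrays of a group, is given with a bound measured against 4.

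Other choices were tried 1 at a time: the experiment as a block, nested in time or shared across times, no filter or a filter at 6, median centring, cyclic loess, a trended and robust variance prior, only the 6 arrays of a time, array weights, a minimum log2 change of 1, counting genes, the median over a gene's probe sets, leaving out each array, and, for lists, the other set tests. Added after the data had been seen were a scaling of each array to its poly-A spike controls, hosts by position, and probe sets whose annotation names a microRNA. The procedure was tested on simulated data of the same size in which 200 probe sets had been changed. Noise there was independent between arrays, with no pairing of the experiments, and 200 is far fewer than were called in the data. At a log2 change of 0.5, 1 and 2 the procedure recovered 25.4, 82.1 and 98.5% of the changed probe sets at 6 h and 29.9, 89.6 and 100% at 24 h. For the difference between the times it recovered 7.46, 53.7 and 90.9%. In these comparisons there were 7, 7 and 5 false calls. Splits of the samples into other groups of 3 were fitted in the same way.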

Results

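The question put to these arrays was which primary microRNA transcripts respond to a glucocorticoid in acute lymphoblastic leukemia cells. CCRF-CEM-C7H2 cells with 100 nM dexamethasone were compared with ethanol controls after 6 h and after 24 h, with 3 independent experiments per time. The glucocorticoid response of all measured genes is given first, then that of the host genes of microRNAs. A scaling to the poly-A spike controls, chosen after these were seen to be higher on the dexamethasone arrays, lowered each log2 change by 0.47 at 6 h and by 0.34 at 24 h. Counts under it are given beside many of the others as counts "on the spike scale", since no value here decides between the scales. The hybridization controls, which are added after labelling, were also higher with dexamethasone, by 0.34 at 6 h and 0.38 at 24 h. Beyond these controls the poly-A spikes differed by 0.13 and -0.0396 on average. Falls on the spike scale can thus not be read as less messenger RNA in the treated cells.

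After 6 h of dexamethasone the strongest rise was that of TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein GILZ. It rose by at least 7.49 (log2) from background (adjusted p = 2.17e-10). TRIB1, a pseudokinase that steers protein degradation, and PFKFB2, which sets the level of fructose 2,6-bisphosphate, left background by at least 4.64 and 4.45. ADM, the precursor of the vasodilator adrenomedullin, rose by at least 2.48. RUNX2, a transcription factor of bone formation (5.45 ± 0.69), TNFSF8, the CD30 ligand (4.62 ± 0.18), PIK3IP1, an inhibitor of phosphatidylinositol 3-kinase (3.77 ± 0.32), and CRISPLD1 (3.64 ± 0.24) completed the largest rises. The adjusted p was 0.00101 for RUNX2 and at most 7.08e-05 for the others. The glucocorticoid receptor gene NR3C1 itself rose from a log2 of 12.14 to 14.08 (1.94 ± 0.09, adjusted p = 5.38e-07).

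The falls at 6 h were smaller. The largest were those of RGMA, a repulsive guidance molecule (-1.71 ± 0.12), and HES1, a transcriptional repressor downstream of NOTCH (-1.66 ± 0.23). They were followed by IER3, an immediate early gene (-1.41 ± 0.25), RAG1, a subunit of the recombinase that joins antigen receptor segments (-1.34 ± 0.28), and SERPINI1, the protease inhibitor neuroserpin (-1.31 ± 0.23). ENDOD1 (-1.16 ± 0.12), the transcription factor MEF2C (-1.15 ± 0.12) and the kinase MAP3K21 (-1.15 ± 0.14) followed, all 8 with an adjusted p of 0.019 or less. MYC, which drives growth and ribosome synthesis, fell by 0.99 ± 0.10 (adjusted p = 0.000262), and CCND3, cyclin D3, differed by -0.07 ± 0.15 (adjusted p = 0.858; -0.54 on the spike scale, adjusted p = 0.0265).

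Of 24 measured glucocorticoid receptor targets 17 rose at 6 h, among them FKBP5, a co-chaperone of the receptor (2.57 ± 0.12), and NFKBIA, the inhibitor of NF-kB (1.59 ± 0.09). TNFAIP3 fell (-0.56 ± 0.12; chosen after its value was seen), and 6 did not pass the test. The list was shifted up (camera adjusted p = 1.07e-22; adjusted p = 0.00226 with an estimated correlation), and 15 of its members rose and 2 fell on the spike scale. Of 19 genes of MYC and ribosome biogenesis 6 fell and none rose (17 and none on the spike scale), for example the ribosome assembly factors NOP16 (-0.78 ± 0.13) and RRP9 (-0.79 ± 0.12) and the RNA polymerase I subunit POLR1B (-0.57 ± 0.11). That list was shifted down (camera adjusted p = 7.62e-05), with an adjusted p of 0.792 with an estimated correlation. In the lysosome and autophagy list 1 of 19 members rose, ULK1, a kinase that starts autophagy (0.94 ± 0.24). In the cell cycle list limma called 0 of 40 members (8 at an unadjusted p under 0.05). With the experiment as a block 3 rose in the lysosome list, and in the cell cycle list 4 rose and 1 fell. Both lists were shifted up on the deposited scale, with camera adjusted p of 0.0429 and 0.04. With an estimated correlation the adjusted p was 0.894 and 0.956, and on the spike scale the mean of both lists turned negative (-0.31 and -0.36), with 10 and 14 members lower.

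The remaining lists did not pass camera at 6 h. Of all 9947 tested genes 6.49% passed the test at this time (271 higher and 375 lower). In the BCL2 family BCL2L11, which encodes the death-promoting protein BIM, rose (1.82 ± 0.12, adjusted p = 1.03e-05) and PMAIP1, also death-promoting, fell (-0.65 ± 0.11), with 16 of 18 members not past the test (1 and 10 on the spike scale; the median of the list was -0.02 and its mean 0.05). Among 9 early response genes of AP-1 and NF-kB the activation marker CD69 (3.23 ± 0.18) and JUN (1.53 ± 0.13) rose, and IER3, IER2 (-0.46 ± 0.12) and JUNB (-0.51 ± 0.13; chosen after its value was seen) fell (2 and 6 on the spike scale). Of 21 T-lineage genes the transcription factor LEF1 rose (0.48 ± 0.07; 0.01 on the spike scale), and RAG1, its partner RAG2 (-0.44 ± 0.09) and the transcription factor BCL11B (-0.88 ± 0.15) fell (1 and 14). HES1 and NOTCH1 (-0.74 ± 0.16) fell in the NOTCH list of 7, and 5 fell on the spike scale. Of 13 interferon-stimulated genes RSAD2, an antiviral enzyme (1.61 ± 0.17), IRF9 (0.92 ± 0.21) and IFI44 (0.74 ± 0.19) rose and none fell, against 2 that rose and 7 that fell on the spike scale. Of 17 genes of the microRNA machinery TNRC6B, a silencing cofactor, rose (0.63 ± 0.14) and XPO5, the exporter of precursor microRNAs, fell (-0.36 ± 0.09; none and 13 on the spike scale). Of 18 glycolysis genes the hexokinase gene HK2 fell (-0.70 ± 0.16; 13 on the spike scale). In the lists of cyclin-dependent kinase inhibitors (7 measured), cholesterol synthesis (13), amino acid and endoplasmic reticulum stress (15), heat shock (8), oxidative phosphorylation (19), B-cell (4), stromal (4) and erythroid markers (1) and housekeeping genes (11), limma called 0 members on the deposited scale, against 1, 1, 2, 1, 1, 1, 0, 0 and 1 at an unadjusted p under 0.05. On the spike scale 6, 9, 10, 7, 19, 3, 2, 0 and 10 of them fell. No myeloid marker reached the filter. With the experiment as a block more members passed. In the BCL2 family 2 rose and 2 fell, among T-lineage genes 3 and 4, interferon-stimulated genes 4 and 1 (OAS1 fell, adjusted p = 0.00620), the microRNA machinery 1 and 3, and glycolysis 1 and 2. Of the lists without a call, 1 cyclin-dependent kinase inhibitor and 2 cholesterol synthesis genes fell under the block. There 1 rose and 1 fell among the stress genes, 1 and 2 among heat shock genes and 1 and 1 among B-cell markers, and 1 housekeeping gene rose.

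In all, 1443 of 23265 probe sets (6.2%) changed at 6 h, 619 up and 824 down, and these included 271 higher and 375 lower genes. A change of at least 2-fold was seen for 258 probe sets (224 up and 34 down). With the experiment as a block 3039 changed (1293 up and 1746 down), 1418 of them among the 1443. With only the 6 arrays of this time 490 changed, and more rose (286) than fell (204). The spike scale gave 15407 changes, 275 up and 15132 down (98.2% lower against 57.1%), 1088 in the same direction on both scales.

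**Figure D1:**
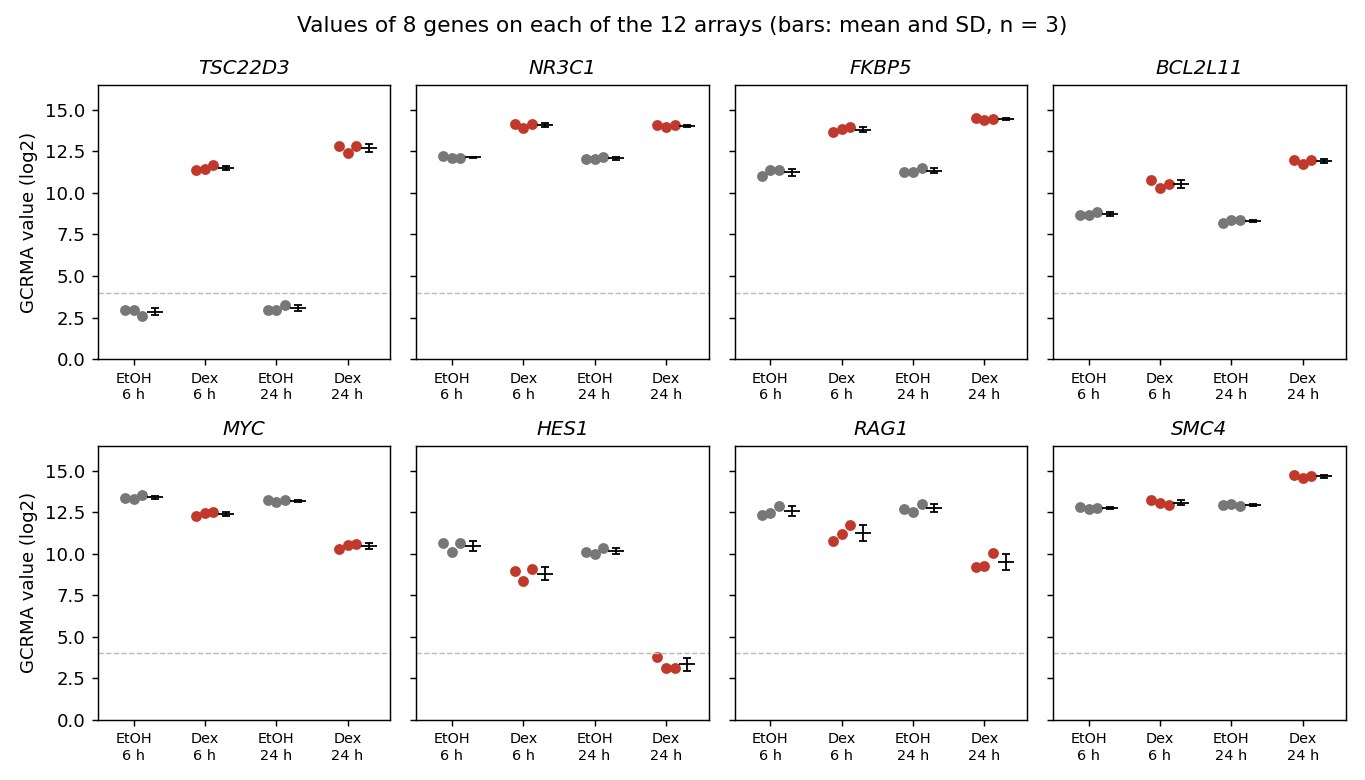
Expression (log2) of named genes on each array, by treatment and time. The dashed line marks a log2 of 4, below which a value counts as background.

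At 6 h each treatment was an array batch of its own, and the 18S ribosomal RNA control differed by -2.27 with dexamethasone (exact p = 0.1, the smallest that 3 against 3 arrays can give). The SD of this control among the ethanol arrays of 6 h was 1.05. The poly-A spikes were higher by 0.47. The count fell below 1443 by over 1.5 times without dexamethasone replicate 1 (955) or 3 (901), or ethanol replicate 0 (906) or 3 (848). Without 1 array some calls ended: RAG1 (adjusted p = 0.0731 without ethanol replicate 3), RAG2 (0.0624, ethanol 1), NOTCH1 (0.0747, ethanol 3), HK2 (0.0913, ethanol 1), JUNB (0.141, ethanol 0) and XPO5 (0.148, ethanol 3). Without dexamethasone replicate 3 those of IRF9 (0.0933), IFI44 (0.130), IER2 (0.138), ULK1 (0.138), TNFAIP3 (0.0632) and TNRC6B (0.0853) ended. These are the highest adjusted p values over the left-out arrays, and 3 to 11 arrays ended each of these calls. The shift of the cell cycle list was lost without dexamethasone replicate 0 or 1 or ethanol replicate 3 (highest adjusted p = 0.154), and that of the lysosome list without dexamethasone replicate 0 or 1, ethanol replicate 0 or 3, or 24 h ethanol replicate 1 or 3 (highest 0.154, without dexamethasone replicate 1).

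After 24 h of dexamethasone several genes at background in the controls had the largest rises. TSC22D3 rose by at least 8.71 and ADM by at least 7.94 (log2) from background. FMO5, a flavin-dependent oxygenase, rose by at least 7.58, PFKFB2 by at least 6.89, CDO1, the cysteine dioxygenase, by at least 6.06, TTN, the giant muscle protein titin, by at least 6.00 and ADGRV1, an adhesion receptor, by at least 5.81. RUNX2 rose by 7.38 ± 0.69, and all 8 had an adjusted p of 8.90e-06 or less. NR3C1 stayed raised, by 1.95 ± 0.09 (adjusted p = 3.82e-08).

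HES1 had the largest fall at 24 h: it went to background, with the log2 change bounded at -6.14 or further down (adjusted p = 7.76e-09). The long noncoding RNA LINC02036 (-4.16 ± 0.21), CCDC78 (-3.97 ± 0.38), the transcription factor BATF3 (-3.69 ± 0.29), RGMA (-3.58 ± 0.12), RGS16, which shortens G-protein signals (-3.38 ± 0.24), the transporter SLC16A9 (-3.34 ± 0.27) and the ribosome assembly factor RRP12 (-3.30 ± 0.23) followed, with an adjusted p of 1.14e-05 or less. MYC fell by 2.72 ± 0.10 (adjusted p = 1.60e-08). CCND3 was lower by a log2 difference of -0.39 ± 0.15 (adjusted p = 0.0504, and 0.0133 with the experiment as a block; -0.73 on the spike scale, adjusted p = 0.00588).

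Of the 24 glucocorticoid receptor targets 19 rose and none fell at 24 h, with FKBP5 at 3.13 ± 0.12 and NFKBIA at 2.3 ± 0.09 (18 and 2 on the spike scale). This list was shifted up (camera adjusted p = 2.99e-11; adjusted p = 0.0242 with an estimated correlation). Of the 19 genes of MYC and ribosome biogenesis 18 fell and none rose on both scales, for example NOP16 (-2.3 ± 0.13), POLR1B (-1.93 ± 0.11) and WDR43, a factor for the small ribosomal subunit (-1.64 ± 0.09). Of 19 lysosome and autophagy genes 12 rose and none fell (10 and 1 on the spike scale), with GABARAPL1, a protein of the autophagosome (4.18 ± 0.23), the cholesterol carrier NPC2 (1.18 ± 0.09), the proton pump subunit ATP6V1H (1.12 ± 0.10) and FOXO3, a transcription factor of starvation and stress (1.00 ± 0.08). Camera called both lists (adjusted p = 1.87e-10 and 4.09e-05), but the adjusted p was 0.227 for each with an estimated correlation.

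None of the other fixed lists passed camera at 24 h. Of all 9947 tested genes 52.0% passed the test at this time (2378 higher and 2797 lower). Counts near these shares do not set a list apart. Cell death genes went both ways: 8 of 18 rose, among them BCL2L11 (3.61 ± 0.12, adjusted p = 6.93e-09), the initiator caspase gene CASP8 (1.39 ± 0.10), APAF1 of the apoptosome (0.90 ± 0.10) and BIRC2, an inhibitor of apoptosis (1.08 ± 0.08). The 5 that fell were the death-promoting BIK (-1.08 ± 0.18), PMAIP1 (-0.65 ± 0.11) and DIABLO (-0.47 ± 0.09) and the protective BCL2 (-0.79 ± 0.23) and BCL2L1 (-0.58 ± 0.08), all 5 chosen after their values were seen. In counts on the spike scale 4 rose and 6 fell. Of 40 cell cycle genes 10 fell, such as the phosphatase gene CDC25A (-1.33 ± 0.13), MCM4 of the replicative helicase (-0.75 ± 0.10), GINS2 (-0.79 ± 0.16) and the mitotic kinase gene TTK (-0.57 ± 0.11). The 4 that rose were TOP2A (0.36 ± 0.12), BUB1B (0.44 ± 0.14), KIF11 (0.30 ± 0.07) and NUSAP1 (0.49 ± 0.11; these 4 chosen after their values were seen). On the spike scale none rose and 18 fell, and with the experiment as a block 8 rose and 14 fell. CDKN1B, which encodes the inhibitor p27 (1.02 ± 0.12), CDKN2D (0.73 ± 0.13) and RBL2 (0.48 ± 0.09; chosen after its value was seen) rose. The kinases CDK4 (-0.95 ± 0.10) and CDK6 (-0.61 ± 0.09) of the same list of 7 fell (1 rose and 4 fell on the spike scale). Median and mean differed in sign for this list (-0.08 and 0.03), the early response genes (-0.40 and 0.45) and the B-cell markers (0.26 and -0.08).

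Of 18 genes of glycolysis and glucose uptake 9 fell, among them HK2 (-1.80 ± 0.16), the glucose transporter SLC2A1 (-1.04 ± 0.11) and the lactate dehydrogenase gene LDHA (-0.80 ± 0.09). The transporter SLC2A3 rose (0.82 ± 0.08), and on the spike scale 15 fell and 1 rose. The list had a camera adjusted p of 0.103, and of 0.0348 with the experiment as a block. With an estimated correlation and no block the adjusted p was 0.854. Of 13 cholesterol synthesis genes 8 fell, with LSS, the lanosterol synthase (-1.18 ± 0.15), and DHCR7 (-1.07 ± 0.18). MSMO1 rose (1.03 ± 0.26; chosen after its value was seen), and on the spike scale 9 fell and 1 rose (9 and 3 with the experiment as a block). Of 19 genes of oxidative phosphorylation 6 fell, such as CYCS, cytochrome c (-0.85 ± 0.07), and CYC1 (-0.79 ± 0.08). COX6C (0.28 ± 0.06) and NDUFB5 (0.29 ± 0.10) rose, both chosen after their values were seen and both negative on the spike scale, where 13 fell (with the experiment as a block 2 rose and 10 fell). ATF3 (-2.65 ± 0.36) and the serine synthesis gene PSAT1 (-1.12 ± 0.16) were among 6 of 15 amino acid and endoplasmic reticulum stress genes that fell, with no rise (7 and none on the spike scale; with the experiment as a block 5 rose and 8 fell). Of 8 heat shock genes 6 fell, among them HSPE1 (-1.37 ± 0.10) and HSP90AB1 (-0.88 ± 0.10), and the co-chaperone BAG3 rose (1.18 ± 0.19), with the same counts on the spike scale.

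T-lineage genes divided at 24 h, with 9 of 21 up and 6 down (4 and 8 on the spike scale, where their mean of 0.09 turned to -0.25). The coreceptor gene CD8A (2.54 ± 0.30), LEF1 (0.98 ± 0.07) and the adaptor LAT (0.80 ± 0.12) rose and RAG1 fell by 3.24 ± 0.28. In the NOTCH list HES1, NOTCH1 (-1.67 ± 0.16), the oncogene LMO2 (-1.39 ± 0.17) and MYB (-0.50 ± 0.09) fell. TAL1 rose (0.28 ± 0.10; chosen after its value was seen; -0.06 on the spike scale, where 5 of the 7 fell). CD69 (4.38 ± 0.18), JUN (3.09 ± 0.13) and NFKB1 (0.48 ± 0.13) rose among 9 early response genes. IER3 (-1.57 ± 0.25), IER2 (-0.80 ± 0.12) and JUNB (-0.43 ± 0.13) fell (2 rose and 6 fell on the spike scale). Of 13 interferon-stimulated genes IFI44 (2.02 ± 0.19), IRF9 (1.90 ± 0.21), RSAD2 (1.07 ± 0.17), IRF7 (0.92 ± 0.22) and IFI6 (0.58 ± 0.16) rose, while MX2 (-0.48 ± 0.13), OAS2 (-0.70 ± 0.20) and OAS1, which went to background, fell (4 and 4 on the spike scale). NFKB1, JUNB, IFI6, MX2, OAS1 and OAS2 were chosen after their values were seen. In the microRNA machinery XPO5 (-1.26 ± 0.09), PRKRA (-0.77 ± 0.08), KHSRP (-0.67 ± 0.10), TARBP2 (-0.62 ± 0.08) and the Argonaute gene AGO2 (-0.45 ± 0.13) fell, and AGO4 (1.26 ± 0.15), TNRC6B (1.09 ± 0.14) and DDX17 (0.44 ± 0.10) rose. KHSRP, TARBP2, AGO2 and DDX17 were chosen after their values were seen, and 2 of the 17 genes rose and 9 fell on the spike scale.

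Few markers of other cell types were bright enough to test (4 B-cell, 4 stromal and 1 erythroid). The B-cell receptor subunit gene CD79A rose (1.55 ± 0.18) and IGHM fell (-2.40 ± 0.33; another of its probe sets was called in the opposite direction). VIM rose (0.34 ± 0.09; 0.00 on the spike scale) and EPCAM fell (-0.57 ± 0.21, adjusted p = 0.0488), and the erythroid marker did not pass the test. On the spike scale 1 B-cell marker rose and 1 fell (2 and 1 with the experiment as a block), and 2 stromal markers fell. Among 11 housekeeping genes GUSB (0.62 ± 0.07) and B2M (0.29 ± 0.07; -0.04 on the spike scale) rose. HPRT1 (-0.46 ± 0.08), PGK1 (-0.42 ± 0.09) and TBP (-0.26 ± 0.08; chosen after its value was seen) fell, and on the spike scale none rose and 4 fell.

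In all, 10997 probe sets (47.3%) changed at 24 h, 5304 up and 5693 down, and 2799 by at least 2-fold (1563 up and 1236 down). They included 2378 higher and 2797 lower genes. The spike scale gave 12291 changes, 2227 up and 10064 down (81.9% lower against 51.8%), 7920 in the same direction on both scales. The 6 arrays of this time lay in 1 batch, with the poly-A spikes higher by 0.34 with dexamethasone (exact p = 0.1) and the 18S control by 0.28 (exact p = 0.3). Of the named calls these ended without 1 array, with the highest adjusted p and the array: EPCAM (0.189), OAS2 (0.0561) and BCL2 (0.0522) without dexamethasone replicate 3, and BUB1B (0.0668), OAS1 (0.111) and TBP (0.0731) without ethanol replicate 2. The same held for TOP2A (0.0999), TAL1 (0.130) and JUNB (0.0754) without ethanol replicate 1, and NDUFB5 (0.105) without ethanol replicate 3, and 1 to 7 arrays ended each.

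**Figure D2:**
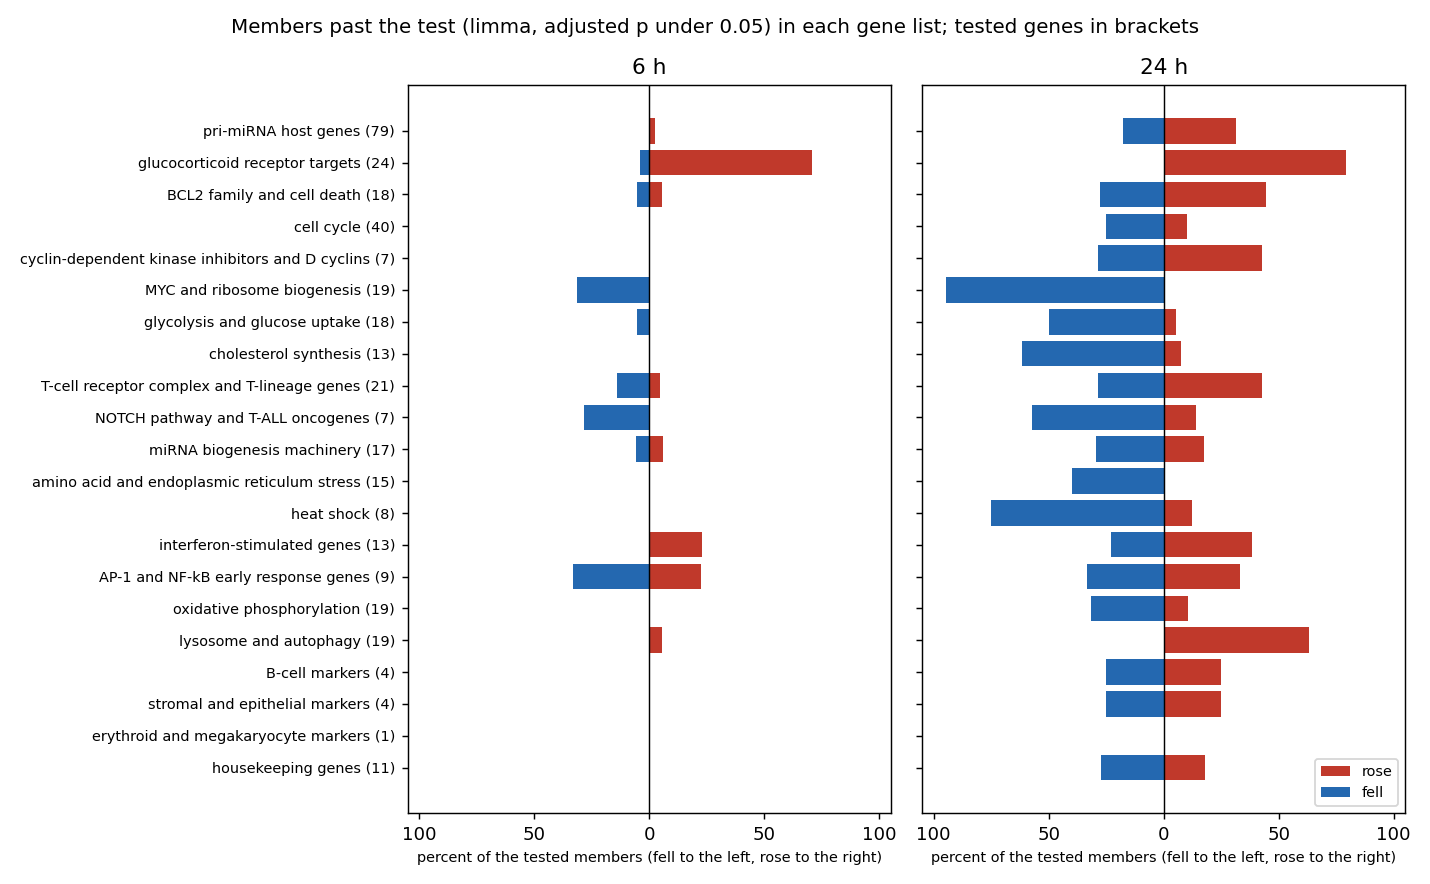
Members of each fixed list that rose or fell at 6 h and at 24 h on the deposited scale. On a scale set by the poly-A spikes the means of all lists but the glucocorticoid receptor targets are negative at 6 h, and those of the T-lineage, cyclin-dependent kinase inhibitor, housekeeping, erythroid and pri-miRNA host lists turn negative at 24 h.

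The responses at 6 h and 24 h ran together. Of the 1443 probe sets called at 6 h 1351 (93.6%) had the same sign at 24 h. At both times 545 were up (141.1 expected of independent calls) and 660 down (201.6 expected), 26 were called in opposite directions (339.3 expected), and 212 passed the test at 6 h but not at 24 h. Across 9947 genes, which are not independent replicates, the log2 changes correlated at Pearson's r = 0.65 and Spearman's rho = 0.57, and between single experiments at r from 0.55 to 0.62. The comparisons share no array.

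Tested directly, the response of 5380 probe sets (23.1%) differed between the times, 2658 in the positive and 2722 in the negative direction, including 2692 genes. The 6 h response in this difference also compares array batches, so a batch difference there enters it and cannot be told from time. The spike scale gave 3299, with 2282 positive and 1017 negative. The largest positive differences (24 h minus 6 h) were those of FMO5 (8.22), TTN (7.40), ADGRV1 (7.40), CDO1 (7.27) and LINC01120 (6.42), all near background without 24 h of dexamethasone, so that their sizes rest on the background level. The largest negative differences were those of HES1 (-5.15, whose size also rests on the background level), CCDC78 (-3.69), LINC02036 (-3.37), RRP12 (-3.30) and the amino acid transporter SLC38A5 (-2.89). SERPINI1 had fallen at 6 h and stood at a difference of 0.05 ± 0.23 at 24 h (chosen after its value was seen; difference between the times 1.36). Glucocorticoid receptor targets (camera adjusted p = 2.05e-06; 0.142 as adjusted p with an estimated correlation), BCL2 family (0.0386; 0.502) and lysosome genes (0.000108; 0.258) were shifted up in this difference and the MYC (2.95e-12; 0.198) and glycolysis lists (0.0119; 0.623) down. With the experiment as a block the cell cycle (adjusted p = 0.0411) and NOTCH lists (0.0366) passed too, with an adjusted p of 0.773 and 0.258 with an estimated correlation and no block. The shift of the BCL2 family was lost without dexamethasone 6 h replicate 0 (0.0935), ethanol 6 h replicate 0 (0.0648) or dexamethasone 24 h replicate 3 (0.0520).

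**Figure D3:**
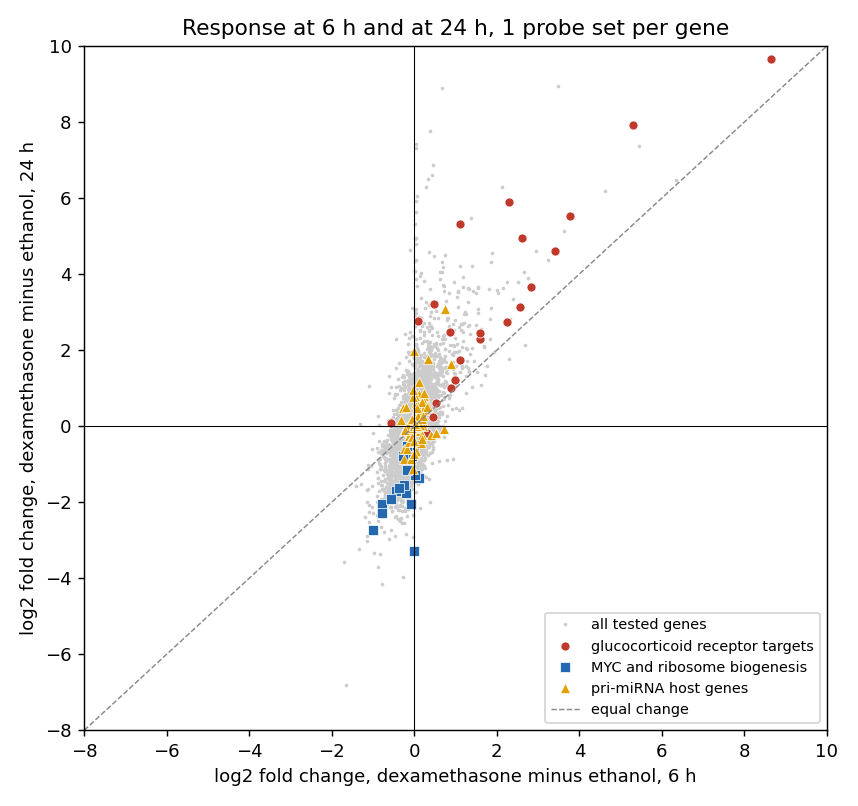
Log2 change with dexamethasone at 24 h against that at 6 h for 9947 genes, 1 probe set each. Genes at background in a group are drawn at their fitted values, and the sizes of their changes rest on the background level.

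The ethanol controls of 24 h and 6 h, which differ in time and in array batch, showed the background of these comparisons. Only 113 probe sets (66 higher and 47 lower at 24 h, 43 genes) passed the test, against 3558 at an unadjusted p under 0.05. This count hung on single arrays. Without 1 ethanol array of 6 h limma called 0 (replicate 0; 2789 at an unadjusted p under 0.05), 267 (replicate 1) or 22 (replicate 3), and without 1 of 24 h 8 (replicate 1), 2 (replicate 2) or 21 (replicate 3). With array weights it called 479, and on the spike scale 37 (11 higher and 26 lower). Camera put the cholesterol synthesis list higher at 24 h (mean log2 difference 0.62, adjusted p = 3.37e-07), the cell cycle list higher (0.01) and the MYC list lower (0.00182), with an adjusted p of 0.587, 0.834 and 0.834 with an estimated correlation.

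Among host genes of microRNAs PRKCA, the gene of protein kinase C alpha, rose at 6 h by 0.90 ± 0.10 (adjusted p = 0.000529). It holds MIR634. Of 130 listed hosts 79 were tested, and PRKCA was the 1 host called at 6 h with p values adjusted over the list alone. Over all tested probe sets TMEM245 passed as well (0.31 ± 0.07, adjusted p = 0.0350, and 0.0658 over the list alone; chosen after its value was seen; -0.16 on the spike scale). The calls over all probe sets were 2.53% of the tested hosts, against 6.49% of all tested genes. At an unadjusted p under 0.05 there were 14 hosts. Over the list alone 8 were called (2 up and 6 down) with the median over a gene's probe sets, and 5 (3 up and 2 down) with no filter or with a trended and robust variance prior. With the experiment as a block PRKCA and ZBTB20 (log2 difference 0.76, adjusted p = 0.00287 over the list alone) were called, and over all probe sets 6 rose and 3 fell. Without dexamethasone 6 h replicate 3 there were 3 calls and without dexamethasone 24 h replicate 3 there were 2, while TMEM245 was lost without each of 6 arrays in turn (highest 0.100, without ethanol 6 h replicate 0). With the spike scale 1 host rose and 51 fell over all probe sets.

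By 24 h 39 of the 79 hosts (49.4%, against 52.0% of all tested genes) had changed, 25 up and 14 down, both with p values adjusted over the list alone and over all probe sets. The largest rises were those of ZBTB20, a zinc finger repressor that holds MIR568 and MIR4796 (3.08 ± 0.32, adjusted p = 1.73e-05), and ATAD2, a chromatin factor with MIR548AA1 and MIR548D1 in its span (1.96 ± 0.15). They were followed by SMC4, a condensin subunit that holds MIR15B and MIR16-2 (1.75 ± 0.09), PRKCA (1.64 ± 0.10) and CTDSP2, a phosphatase gene that holds MIR26A2 (1.16 ± 0.11). CHLSN, with MIR339, had the largest fall (-1.12 ± 0.16, adjusted p = 0.000218). These 6 changed by at least 2-fold. Further falls were those of GATAD2A with MIR640 (-0.87 ± 0.08), SREBF1, the regulator of lipid synthesis, with MIR33B (-0.87 ± 0.18), DENND1A with MIR601 (-0.74 ± 0.22; lost without each of 3 arrays in turn, highest adjusted p = 0.0733 without dexamethasone 24 h replicate 3) and ABCF1 (-0.68 ± 0.06). In ABCF1 MIR877 is a mirtron, an intron that is spliced out as a precursor microRNA. MCM7, with MIR25, MIR93 and MIR106B, fell by 0.43 ± 0.11, and DLEU2, with MIR15A and MIR16-1, rose by 0.43 ± 0.14 (0.09 on the spike scale, adjusted p = 0.730), while another of its 6 probe sets was called in the opposite direction. Both were chosen after their values were seen, and DLEU2 lost its call without each of 5 arrays in turn (highest adjusted p = 0.0722, without dexamethasone 24 h replicate 3).

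The host list as a whole was not shifted at 24 h (camera adjusted p = 0.273; 0.854 as adjusted p with an estimated correlation), and its mean of 0.16 turned to -0.18 on the spike scale, where 9 hosts rose and 28 fell. The response of 20 hosts differed between the times over the list alone (13 up and 7 down; 18 over all probe sets). Hosts were also taken by position in the gene table, strand not considered and chosen after the data had been seen. Of these 585 genes 43 changed at 6 h (24 up and 19 down, 7.35%) and 325 at 24 h (158 up and 167 down, 55.6%). An array of this kind reads the host transcript, and mature microRNAs were not measured.

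**Figure D4:**
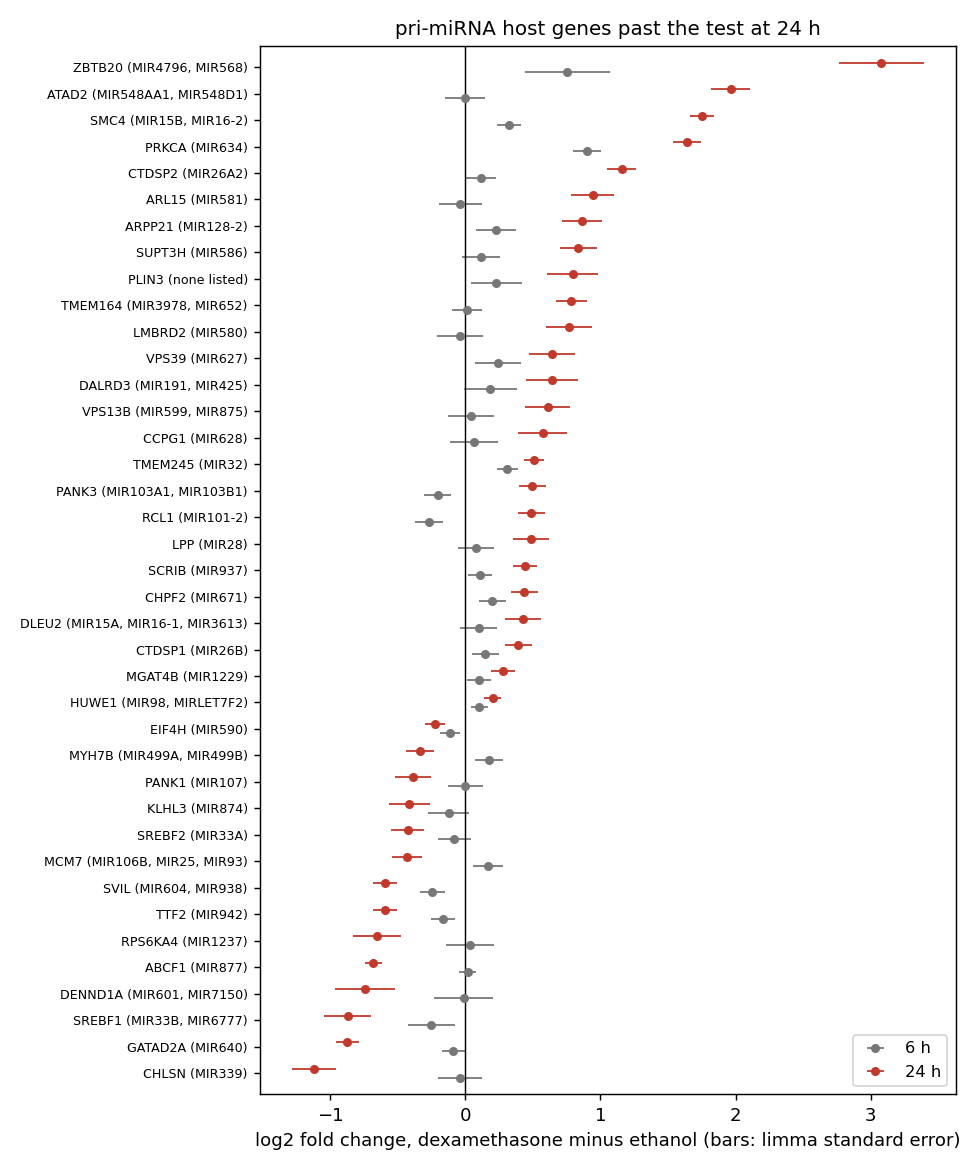
Log2 change at 6 h and 24 h of the 39 pri-miRNA host genes past the test at 24 h, on the deposited scale, with the microRNAs in their spans. The genes were picked by the 24 h test (p values adjusted over the list alone), which favours larger changes at 24 h. The mean of all 79 hosts at 24 h is positive on this scale and negative on the scale set by the poly-A spikes.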

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

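The tests of the array batches at 6 h and of the control probe sets were chosen after these results had been seen. The tests of the difference between the times and the splits of the samples were planned.

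Of 139 genes named in the report and the observations 102 had a response that differed between the times by limma's test of the difference (highest adjusted p among them 0.0431), and 83 of these had the same direction at both times and the larger size at 24 h. Most of the 139 were named for the size or p of their changes, some for this difference itself. These counts therefore follow in part from the choice of genes. The array batches of the 6 h comparison enter each of these differences too, and cannot be told from time. Of all 9947 tested genes 2692 passed the same test. The largest positive differences of the log2 changes (24 h minus 6 h) were FMO5 8.22, TTN 7.40, ADGRV1 7.40, CDO1 7.27, LINC01120 6.42, TP53INP1 6.16, NTN4 5.99, ADM 5.46, GABARAPL1 3.47 and PFKFB2 2.61. Next came ZBTB20 2.32, ATAD2 1.97, BCL2L11 1.79, PIK3IP1 1.77, JUN 1.56, TNFSF8 1.55, CRISPLD1 1.5, SMC4 1.43, CD8A 1.41 and SERPINI1 1.36. These were followed by IFI44 1.27, CDKN2D 1.22, CASP8 1.20, ULK1 1.20, NPC2 1.18, CD69 1.14, CD79A 1.14, CTDSP2 1.04, ATP6V1H 1.03 and AGO4 1.02. Further positive differences were TSC22D3 0.99, IRF9 0.98, FOXO3 0.97, BAG3 0.87, CDKN1B 0.84, IFI6 0.83, BIRC2 0.82, PRKCA 0.74, APAF1 0.73 and NFKBIA 0.71. Smaller ones were SLC2A3 0.67, TNFAIP3 0.63, FKBP5 0.56, DDX17 0.51, LEF1 0.50, RBL2 0.43, RAG2 0.41, GUSB 0.38, COX6C 0.36 and B2M 0.30. The largest negative differences were HES1 -5.15, CCDC78 -3.69, LINC02036 -3.37, RRP12 -3.30, SLC38A5 -2.89, BATF3 -2.82, RGS16 -2.54, VARS1 -2.37, SLC16A9 -2.36, IGHM -1.93 and RAG1 -1.90. After these came RGMA -1.87, ENDOD1 -1.87, ATF3 -1.85, MYC -1.73, POLR3G -1.61, NOP16 -1.52, POLR1B -1.36, TIMM8A -1.33, RRP9 -1.27, WDR43 -1.25 and LMO2 -1.22. Then followed LSS -1.15, HK2 -1.10, DHODH -1.10, CHLSN -1.08, DHCR7 -1.07, CDC25A -1.04, HSPE1 -1.03, PSAT1 -0.96, NOTCH1 -0.93, XPO5 -0.89 and MAP3K21 -0.84. Further negative differences were LDHA -0.83, CYC1 -0.82, CDK4 -0.81, GATAD2A -0.78, GINS2 -0.76, KHSRP -0.72, HSP90AB1 -0.71, ABCF1 -0.70, MCM4 -0.70, CYCS -0.68 and SLC2A1 -0.64. The smallest were MCM7 -0.60, TARBP2 -0.59, CDK6 -0.53, MEF2C -0.53, PRKRA -0.52, HPRT1 -0.51, PGK1 -0.40 and BCL2L1 -0.36. Differences of genes at background in a group rest on the background level. Among the fixed lists the mean difference was 1.17 for glucocorticoid receptor targets, 0.31 for the BCL2 family, 0.67 for lysosome and autophagy, -1.21 for MYC and ribosome biogenesis and -0.39 for glycolysis and glucose uptake, none past the threshold with an estimated correlation.

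Control probe sets also differed between the treatments. The poly-A spikes were higher with dexamethasone by 0.47 at 6 h and 0.34 at 24 h, the hybridization controls by 0.34 and 0.38, each in 3 of 3 experiments (exact p = 0.1, the smallest that 3 against 3 arrays can give), and the 18S ribosomal RNA control by 0.28 at 24 h, in 2 of 3 (exact p = 0.3). At 6 h the 18S control differed by -2.27, lower in 3 of 3 (exact p = 0.1). The 3' minus 5' signals of ACTB and GAPDH, read for RNA integrity, differed by -0.00448 and 0.0502 at 6 h (exact p = 1 and 0.1) and by -0.11 and 0.00937 at 24 h (exact p = 0.2 and 0.8). No exact p of these 10 differences is under 0.05, adjusted or not.

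Splits of 6 arrays into 3 and 3 are 10, too few for a share under 0.05. For the probe sets at 6 h 1 split, the real one, gave as many (1443; highest other 2, and 0 among the 3 others that part all pairs of same-numbered arrays), at 24 h again 1 (10997; highest other 0), for the ethanol controls 1 (113; highest other 0), and for the pri-miRNA hosts 1 at 6 h (1; highest other 0) and 1 at 24 h (39; highest other 0). For the difference between the times, where the 6 experiments were divided anew over the times, 1 split gave as many probe sets (5380; highest other 0). In each other split both groups mix arrays of both kinds, so a large real difference swells the spread within groups. Low counts there were thus largely set in advance and do not measure chance. Lists were not so set apart: 3 of the 10 splits gave as many as the 4 lists at 6 h (highest other 5, and 3 among those that part all pairs), 10 as many as the 3 lists at 24 h (highest other 6, and 4 among those that part all pairs) and 3 as many as the 5 lists for the difference (highest other 6). The camera counts of lists are thus reached by other groupings too. Those groupings keep a part of the real difference, so this does not put the lists at the level of chance. With the arrays of 24 h divided anew, the correlation of the responses (taken without its sign) was largest in 1 split, the real one (0.65; highest other 0.62, which also parts all pairs). These splits keep a part of the treatment difference, so that 0.62 is no value without a response. With the experiments divided anew over the times all 9 other splits gave more than 0.65.

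At 6 h each treatment was an array batch of its own. At 24 h all arrays lay in 1 batch. A batch difference particular to 6 h, with no treatment effect, would leave the 24 h signs at about even shares. Of the 1443 probe sets 93.6% had the same sign at 24 h, against 68.3% of all tested, which argues against such a difference alone. Poly-A and hybridization controls were higher with dexamethasone at both times. A technical difference shared by both times would also give equal signs, and this share does not test it. Of the 238 probe sets not called in the same direction at 24 h 61.3% (146) had the same sign, but they were picked by their outcome at 24 h, so that this share decides nothing and the cause of their calls stays open. An early response to dexamethasone may account for a part of the calls: 70.8% of the measured glucocorticoid receptor targets rose at 6 h, against 2.72% of all genes. That list bears on rises alone, and how the calls divide between treatment and batch cannot be told from it.

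For the higher poly-A spikes a candidate explanation is brighter hybridization of the dexamethasone arrays relative to their normalization. The hybridization controls, which are added after labelling, were higher with dexamethasone in 6 of 6 experiments. Less messenger RNA per total RNA in the treated cells would raise the poly-A spikes further than the hybridization controls. The difference of these was -0.0396 on average at 24 h (from -0.72 to 0.35 over the experiments) and 0.13 at 6 h (from -0.14 to 0.27, higher in 2 of 3 experiments), so that this explanation stays open. No value decides whether the deposited or the spike scale is nearer to the amounts per cell.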

How the results depend on the processing

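The scaling to the poly-A spikes and the hosts by position or by annotation were chosen after the data had been seen, and the other alternatives were planned. Of the values of the 10 main results under the alternatives 184 stayed (counts within 1.5 times) and 54 moved. Whether more rose or more fell also turned in some, for example at 6 h with only the 6 arrays of that time (286 up and 204 down) and at 24 h with cyclic loess (5843 up and 5484 down). Of 247 values of single genes 163 kept their direction and their side of the threshold under all alternatives run. Past the threshold or not, 35 changed sign under at least 1 alternative, 32 of them on the spike scale, and 11 of these were past the threshold on either scale. The signal over background limits genes below a log2 of 4, and 3 arrays per group limit small changes: of simulated log2 changes of 0.5 25.4 to 29.9% were recovered within a time. Except for counts that fell by a stricter threshold or by fewer features tested, the cause was not tested.

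At 6 h the 1443 probe sets became 3039 with the block nested in time, 2219 with the block shared across times, 490 with only the 6 arrays of that time, 258 with a log2 change of at least 1, 765 counting genes, 15407 on the spike scale, and 848 to 1385 without 1 array. Counting genes here means a fit of 1 probe set per gene, with p values adjusted over the 9947 genes alone. The gene counts given in the results used the adjustment over all tested probe sets and therefore differ. At 24 h the 10997 became 2799 with a log2 change of at least 1 and 5430 counting genes, and 9303 to 11228 without 1 array. The 5380 of the difference became 1730, 2965 and, on the spike scale, 3299, and 4217 to 5545 without 1 array. The 113 between the ethanol controls became 170 with the shared block, 190 with a filter at 6, 282 with trend and robust, 479 with array weights, 19 with a log2 change of at least 1, 75 counting genes, 37 on the spike scale, and 0 (limma) to 267 without 1 array. The 1 host at 6 h became 2 with either block or cyclic loess, 5 with no filter or with trend and robust, 8 with the median over probe sets, 43 by position, 4 by annotation, 53 on the spike scale, and 1 to 3 without 1 array. The 39 hosts at 24 h became 325 by position and 110 by annotation (of 184 probe sets), and 31 to 39 without 1 array. The 4 lists at 6 h became 2 with array weights, 1 with an estimated correlation, 2 on the spike scale, and 2 to 4 without 1 array. The 3 lists at 24 h became 5 with no filter, 1 with an estimated correlation and 15 with fry, which tests the genes of a list by themselves, and stayed at 3 without each array. The 5 lists of the difference became 0 with an estimated correlation and 8 with fry, and 4 to 7 without 1 array. The correlation of 0.65 ranged from 0.61 to 0.65 without 1 array. The sign of these 11 on the spike scale turned at 6 h for TAL1 (-0.34), NDUFV1 (-0.34), EBF1 (-0.46), VIM (-0.38), ACTB (-0.34) and TMEM245 (-0.16), and at 24 h for B2M (-0.0444), TAL1 (-0.0558), KIF11 (-0.0378), COX6C (-0.0581) and NDUFB5 (-0.0519). Not run were the nested block for the ethanol controls, which are confounded with it, a batch term at 6 h, and same-strand hosts, since the table used gives no strand.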

Other observations

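The tests of the cholesterol synthesis genes and the search for genes at background elsewhere were chosen after their results had been seen, and the 8 further lists of growth genes were written with their predictions before those lists were tested but after the fall of MYC had been seen.

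Further groups of biosynthesis genes were lower at 24 h (1 gene each of the purine and pyrimidine and of the RNA polymerase list is also in a fixed list). All 15 measured genes of purine and pyrimidine synthesis fell (mean log2 change -1.15), with DHODH, the mitochondrial enzyme of pyrimidine synthesis, at -2.13 ± 0.13. Of 16 subunits of RNA polymerases I and III 14 fell and 1 rose (-1.03; POLR3G -2.50 ± 0.19), of 17 aminoacyl-tRNA synthetases 15 fell (-0.88; VARS1 -1.99 ± 0.20), and of 21 genes of mitochondrial protein import 19 fell (-0.82; TIMM8A -1.70 ± 0.11). All 7 subunits of the chaperonin CCT fell (-0.74), and of 75 mitochondrial ribosomal proteins 55 fell and 2 rose (-0.53). Of 34 proteasome subunits 17 fell and 1 rose (-0.20). Cytosolic ribosomal proteins had a mean of -0.0618, with 7 of 56 lower and 1 higher. The hypothesis that these groups fall together with MYC predicted a downward shift for each. Camera called 7 of the 8 (adjusted p from 4.3e-11 to 0.00252) and not the cytosolic ribosomal proteins (0.3). With an estimated correlation none passed (adjusted p from 0.108 to 0.613). The spike scale lowers all 8 means further. At 6 h, when MYC had already fallen, camera put 5 of the 8 lower (adjusted p from 3.11e-05 to 0.0216; from 0.322 to 0.526 as adjusted p with an estimated correlation). The aminoacyl-tRNA synthetases (mean -0.0170, adjusted p = 0.689), the proteasome subunits (-0.0410, 0.295) and the cytosolic ribosomal proteins (-0.0115, 0.862) were not called at 6 h. A joint fall of these groups with MYC may describe 7 of the lists at 24 h and 5 at 6 h, but these data hold no test of MYC as its cause.

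Dexamethasone for 24 h was the 1 condition with probe sets bright there and at background on all other arrays. Here 43 probe sets, with the symbols of 31 genes, had a log2 of at least 6 on all 3 of its arrays and were below 4 on the other 9, and for each of the other 3 groups this count was 0 (a count without a test). Other probe sets of the same genes can differ, as for RUNX2, where another one rose at 6 h. Besides probe sets of FMO5, TTN, ADGRV1 and CDO1, the group held those of NTN4, a netrin of basement membranes (at least 5.11 above background, log2), and TP53INP1, a regulator of stress responses and autophagy (at least 5.12). The reverse, at background on these 3 arrays alone, was found for 1 probe set, of HES1. The counts of 0 in the other groups say little. Between the ethanol groups 113 probe sets differed, and 545 of the 619 probe sets up at 6 h were also up at 24 h. Few probe sets could thus be bright in 1 of those groups alone.

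Cholesterol synthesis genes were lower with dexamethasone than with ethanol at 24 h (mean log2 change of 13 genes -0.44), though camera did not call the list (adjusted p = 0.198). A single aberrant array is argued against: without the array whose loss brings the mean nearest to 0 it was -0.38. The dexamethasone arrays were 0.31 higher at 24 h than at 6 h, where a fall from their own 6 h level predicted lower values. The ethanol arrays were 0.62 higher at 24 h than at 6 h. Both steps cross array batches, and a batch difference could hide a fall, so the step of the dexamethasone arrays does not decide it. A rise in the controls that the treated cells shared in part is a candidate explanation of the lower level, and it stays open too. Culture time and array batch both differ between the times and cannot be told apart here.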
